A study of Sus scrofa with 26 samples.

How the data were processed

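The data were bulk mRNA sequencing profiles of neonatal porcine ileal epithelial monolayers, which are flat cell layers grown from enteroids, the organoids that crypts of the small intestine form in culture. Cells of 6 pigs (numbered P332, P333, P335, P336, P337 and P342 in the labels) were plated in wells with media alone or with Human Placental Extract (HPE) at 0.075 mg/mL, and media and treatment were renewed daily. Each pig gave 2 control and 2 HPE wells, except pig P342, which gave 3 of each, so that 26 libraries were used, 13 per arm. Libraries were made with a directional kit, which keeps the strand of each transcript, per the labels' protocols. The labels used here name no plate, day, passage or sequencing batch for any well.

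Per the submitters' processing notes, Trim Galore 0.6.7, STAR 2.7.9a and Salmon 1.10.1 were used with the pig genome build Sscrofa11.1. The parameters, the annotation release and how the aligner and the counter were joined are not given in the sources used here. The deposited tables hold 1 line for each of 58461 Ensembl transcripts, per the file headers and identifiers. The estimated counts in the deposited tables are Salmon's estimated reads per transcript, per the file headers, and are not scaled to depth. Between 30.93% and 35.15% of the values of a well were not whole (tolerance 1e-06), because Salmon divides a read that fits several transcripts between them. TPM in the deposited tables is the abundance of a transcript per unit of effective length, scaled to 1 total in every library, per the file headers. The other columns, transcript length and effective length in bases, were deposited with them per the file headers. Estimated reads per well ran from 25461499 to 69281189 with a median of 42117482, and 28426 to 32377 transcripts had at least 1 estimated read.

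The tests had been fixed per gene before the data were examined, with the transcript as the fallback unit. The reference tables at hand pair pig gene identifiers (15623) and RefSeq genes (30371) with symbols, and 0 of the transcript identifiers matched either table. Counts could therefore not be summed per gene, no transcript could be given a gene name, and every test was run per transcript. The 30 gene lists and 10 single genes fixed before the data were examined, the gene set tests, the list scores, the mitochondrial share and the check for other cell types were left out for the same reason. A change in a transcript can be a change of its gene or of the share of that gene's reads given to it, and the 2 cannot be separated here.

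The rule for naming single genes, also fixed before the data were examined, asked for a symbol and could not be followed. It was replaced, after the data were seen, by 4 transcripts with a mean log2 CPM of at least 1. For the change over 6 pigs, these are the transcripts with the smallest p in each direction. Only those with the same sign of change in the summed counts of all 6 pigs were eligible. For the difference between pigs, they are those with the smallest interaction p whose largest change in any pig was upward or downward. That pig was P342 for both. The 4 transcripts are given by their identifier.

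The pig is the replicate, since the wells of a pig are not independent animals, and it pairs the arms, since control and HPE wells came from the same animals. For the comparison of the arms over pigs, estimated counts were summed over the wells of a pig and arm (12 sums of 66579862 to 139825463 reads), rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. The settings were TMM scaling, the default filter on low counts, the quasi-likelihood test of treatment with pig as a block, and a Benjamini-Hochberg adjusted p under 0.05. The change within each pig was tested by a contrast in 1 fit of all 26 wells with a mean per pig and arm, which takes the spread from the wells of all pigs. The pig-by-treatment interaction was tested over its 5 terms in the same wells, and differences between pigs over the 13 control wells. P-values from these tests on wells measure only the spread between wells of one pig and arm, which holds no animal-to-animal spread. Shares of variance are sums of squares of log2 CPM (prior count 2) with a jackknife SE over pigs. Correlations across transcripts used the 18895 transcripts with a mean log2 CPM of at least 1 over the 26 wells. The log2 change summed over pigs and the axes from control to HPE level used the same transcripts. Library measures were compared by an exact two-sided sign-flip permutation test over 6 pigs (64 sign patterns). Figures were drawn with matplotlib 3.10.9.

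Well numbers did not pair control with HPE wells of a pig. The deviations of same-numbered wells from their arm's mean correlated across transcripts at -0.07 to 0.068. No 2 wells of a pig and arm were alike within sampling noise, since the chi-square per degree of freedom of the 16 such pairs was 16.26 to 49.81.

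The edgeR steps were tested on simulated counts with the means and library sizes of these wells, drawn independently per transcript. The changed transcripts were taken from those with a mean log2 CPM of at least 1, so recovery among all tested transcripts was not measured. Over 6 pigs, 45 of 100 transcripts changed 2-fold and 83 of 100 changed 4-fold were recovered, with 6 false calls among 30454 transcripts. Within pig P332, with 2 wells per arm, 59 of 100 and 82 of 100 were recovered with 5 false calls among 29577, and within pig P342, with 3 wells per arm, 58 of 100 and 92 of 100 with 3 false calls among 29521. Alternatives were other size factors, other count filters, DESeq2 1.42.0, limma 3.58.1 on voom-weighted counts or on log2(TPM + 1) and log2(TPM + 0.1), an offset for effective length, other blocks, and each pig left out in turn. Chosen after the data were seen were each well left out in turn, all wells thinned to the depth of the shallowest, the 100 most abundant transcripts removed, and only transcripts with whole-number counts in every well.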

Results

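Transcript levels were measured in 26 wells of neonatal pig ileal epithelial monolayers, 13 with media alone and 13 with HPE at 0.075 mg/mL, from 6 pigs that each contributed both arms. Monolayers were harvested when nearly confluent. HPE is an extract of human placenta, and the study's title places the comparison in the setting of epithelial repair in newborns. Depth ran from 25461499 estimated reads, in HPE well 2 of pig P337, to 69281189, in control well 1 of pig P336. The files name Ensembl transcripts and do not pair them with genes, so the results are given per transcript and no gene or pathway is named.

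Over all pairs of wells, correlation was higher within a pig than within an arm, but not in every pig. The median Pearson correlation of log2 CPM across transcripts was 0.912 for the 16 pairs of wells of the same pig and arm and 0.877 for the 29 pairs of the same pig in opposite arms. It was 0.834 for the 140 pairs of wells of different pigs in the same arm, and 0.834 again for the 140 pairs in opposite arms. Pig by pig, the median between opposite arms was 0.89 to 0.93 in pigs P332, P333, P335 and P336. In pigs P337 and P342 it was 0.827 and 0.832, no higher than between different pigs in the same arm. Of the variance of log2 CPM, 37.6% ± 4.9 (jackknife SE, n = 6 pigs) lay between pigs and 38.7% ± 3.4 between wells of one pig and arm. Treatment took 4.91% ± 1.9 and the pig-by-treatment term 18.8% ± 1.0. The degrees of freedom were 5 for pigs, 14 for wells, 1 for treatment and 5 for pig by treatment. The shares are not divided by them and so do not rank the sources, and part of each share is spread between wells. Without pig P333 the share of treatment was 7.1%. The first pair of shares depended on the scale: on log2(TPM + 1), 52.3% lay between pigs and 21.6% between wells.

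**Figure D1:**
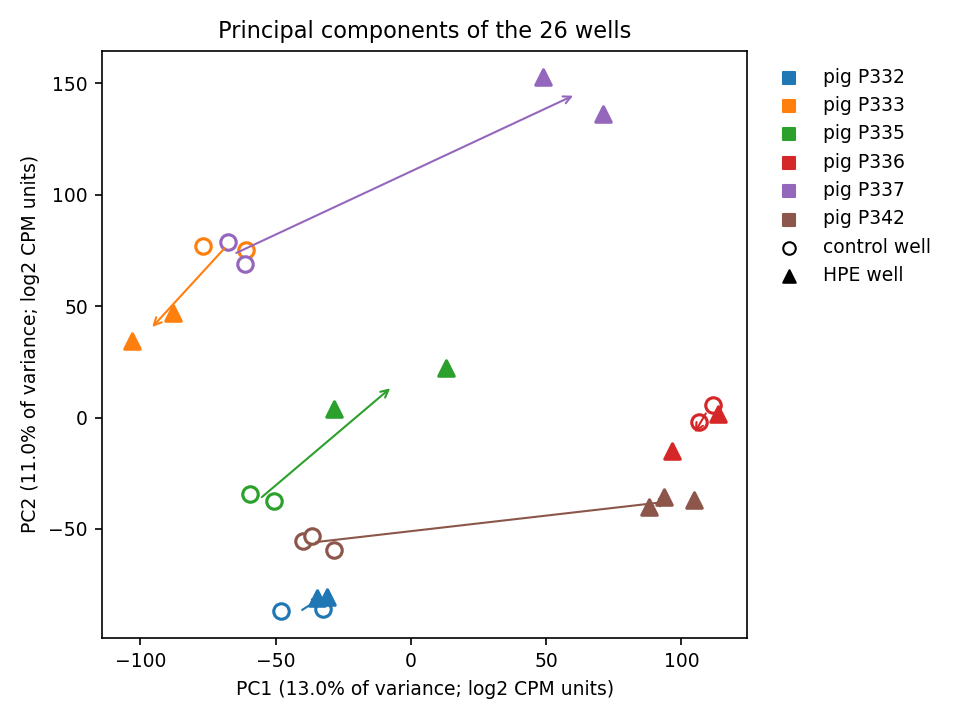
Scores of the 26 wells on the first (horizontal, 13% of variance) and second (vertical, 11% of variance) principal components of log2 CPM. Colour gives the pig, open circles are control wells, filled triangles are HPE wells, and each arrow runs from a pig's control mean to its HPE mean; arrows of pigs P337 and P342 are 143 and 132 units long and those of pigs P332 and P336 are 9.32 and 9.44.

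The arms did not differ detectably in library measures when compared within pigs. Total estimated reads per pig were 101153723 ± 24944771 (SD, n = 6 pigs) in control and 96297599 ± 21935254 in HPE sums (exact two-sided sign-flip permutation test, p = 0.594). The number of transcripts detected was 34940 ± 920 and 34430 ± 1220 (exact permutation p = 0.3125). The 100 most abundant transcripts held 15.47% ± 0.91 and 16.02% ± 1.8 of reads (exact permutation p = 0.469), and the TMM factor was 1.017 ± 0.0304 and 0.9855 ± 0.0604 (exact permutation p = 0.469). Adjusted over the 4 measures, each p was 0.594.

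The first question was which transcripts changed with HPE in the same direction across animals. Of 31900 transcripts tested with edgeR over the 6 pigs, 0 passed an adjusted p of 0.05. The smallest adjusted p was 0.774, and 1214 transcripts (3.806%) had an unadjusted p under 0.05. Other tools differed in this count. DESeq2 on the same 12 sums called 91 transcripts, 51 higher and 40 lower with HPE. With the 26 wells as separate libraries and pig as a block, edgeR called 1609, and limma-voom with pig as a random effect called 1712. Both treat wells as replicates, and their error pools the spread between wells with the pig-by-treatment differences. On the same 26 wells edgeR called 0 with pig and well number together as block (5725 unadjusted p under 0.05) and 0 without a block (3094 unadjusted). The count of unadjusted p under 0.05 was 2711 without pig P333, 672 without pig P335, 649 without pig P337 and 720 without pig P342. Among 18842 transcripts with a mean log2 CPM of at least 1, the median SD of the log2 change over the 6 pigs was 0.376, which gave a median SE of 0.153. The median size of the mean log2 change was 0.157, and it was not tested against the size that noise alone would give.

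The transcripts that the rule chose in each direction over the 6 pigs are given as values, since neither passed the threshold in the edgeR test of the 12 sums. ENSSSCT00000038596, 8639 bases long, stood at 5.03 CPM ± 1.72 (SD, n = 6 pigs) in control and 8.11 CPM ± 1.67 in HPE wells. Its log2 change was 0.78 ± 0.147 (SE; edgeR adjusted p = 0.774), with higher HPE means in 6 of 6 pigs, and it was 0.34 on log2(TPM + 1) with limma. ENSSSCT00000041298, 2998 bases long, stood at 7.72 CPM ± 8.29 in control and 3.01 CPM ± 4.24 in HPE wells, with a log2 change of -1.41 ± 0.29 (SE; edgeR adjusted p = 0.774). Its mean over wells was lower with HPE in 5 of 6 pigs and was 1.71 CPM in control and 1.83 CPM in HPE wells of pig P332. Its log2 change was -0.62 with well number 2 left out of every pig and -2.61 with well number 1 left out. Pig P333 stood apart from the others in both arms of this transcript, at 23.8 CPM and 11.6 CPM. DESeq2 gave adjusted p = 0.00321 for ENSSSCT00000038596 and adjusted p = 0.00826 for ENSSSCT00000041298. With the 26 wells as separate libraries, ENSSSCT00000038596 also passed the threshold in edgeR with pig as a block (edgeR adjusted p = 0.0357) and with pig as a random effect (limma-voom adjusted p = 0.0382), but not in edgeR with pig and well number together as block (edgeR adjusted p = 0.19) or without a block (edgeR adjusted p = 0.308). ENSSSCT00000041298 did not (edgeR adjusted p = 0.243, limma-voom adjusted p = 0.715). Neither transcript had whole-number counts in every well, so part of their reads was shared with other transcripts.

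The next question was how large the change with HPE was in each animal. Pig P342 had 10017 of 30784 transcripts past the threshold (4869 higher and 5148 lower with HPE), and pig P337 had 9584 (4824 higher and 4760 lower). Pig P335 had 4140 (2168 higher and 1972 lower) and pig P333 had 1964 (933 higher and 1031 lower). Pig P336 had 12 (4 higher and 8 lower) and pig P332 had 3, all lower. With DESeq2 the counts were 11583 in pig P342, 11324 in pig P337, 6263 in pig P335, 4141 in pig P333, 233 in pig P336 and 321 in pig P332, so the small counts depended most on the tool. The median size of the log2 change among called transcripts was 0.69 in pig P342, 0.78 in pig P337, 0.56 in pig P335 and 0.55 in pig P333. Changes beyond 2-fold numbered 3302 in pig P342 and 3403 in pig P337, against 755 in pig P335 and 406 in pig P333. The median log2 change of all tested transcripts was 0 in each pig, but TMM scaling holds it near 0, so it does not speak to a balance of rises and falls. These tests set the arms against the spread between wells, and the labels used here give no plate or day by which wells of one arm of a pig may have been grown together. With DESeq2 size factors in place of TMM, pig P332 had 2 higher and 3 lower, and the largest move of the split among the other pigs was in pig P335, from 52.4% to 49.1% higher. The smaller counts moved when single wells were left out. The count of pig P333 fell without any 1 of its wells. That of pig P335 fell without HPE well 1 or either control well and rose without HPE well 2. Such a fit leaves a lone well in that arm, so a fall does not show that the well carried the calls. Leaving out any 1 well of pig P332 gave 13 to 25, and pig P336 had 19 without HPE well 1 and 31 without HPE well 2.

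**Figure D2:**
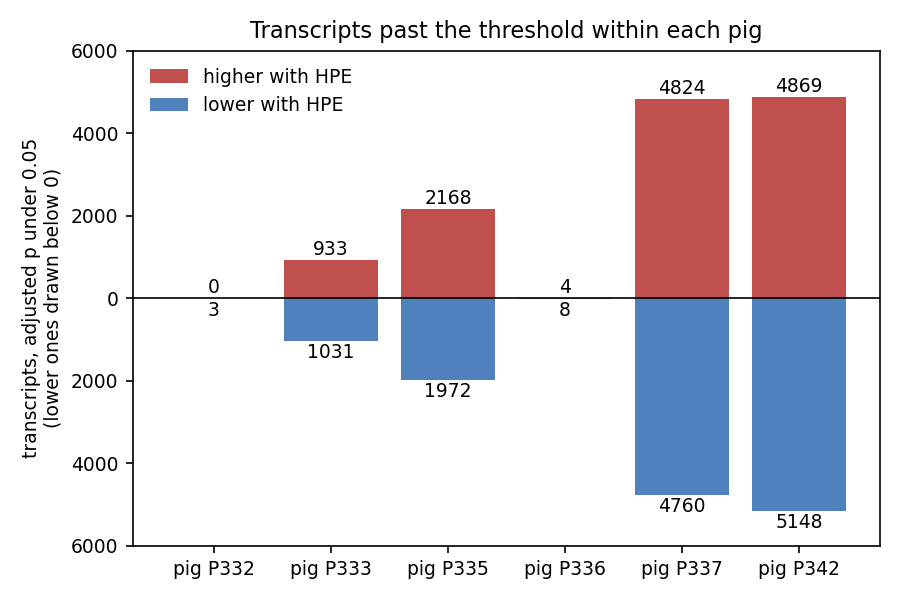
Number of transcripts past an adjusted p of 0.05 for HPE against control within each pig (vertical axis, transcripts), with higher ones drawn above 0 and lower ones below. Pig P337 has 4824 higher and 4760 lower transcripts, and pig P336 has 4 and 8.

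The difference between animals was tested itself. The pig-by-treatment interaction passed the threshold for 10940 of 30784 transcripts (35.54%), and for 7092 without pig P342. ENSSSCT00000016326, 5041 bases long, rose with HPE in pig P342 from 61.4 CPM ± 1.75 (SD, n = 3 wells) to 218 CPM ± 6.3, a log2 change of 1.83 (edgeR adjusted p = 1.45e-09). It also rose in pig P337, from 45.8 CPM ± 1.82 (SD, n = 2 wells) to 79.6 CPM ± 14.5 (edgeR adjusted p = 1.14e-05), and in pig P335, from 81.3 CPM ± 7.83 to 109 CPM ± 5.57 (edgeR adjusted p = 0.00791). In pig P332 it stood at 92.5 CPM ± 4.06 in control and 76.3 CPM ± 5.38 in HPE wells (edgeR adjusted p = 0.632). In pigs P333 and P336 it did not pass the threshold, at 102 and 104 CPM and at 159 and 178 CPM. The interaction had an adjusted p of 4.65e-07. ENSSSCT00000010014, 1072 bases long, fell with HPE in pig P342 from 92.2 CPM ± 1.84 (SD, n = 3 wells) to 48.4 CPM ± 0.883, a log2 change of -0.93 (edgeR adjusted p = 4.11e-10). In pig P333 it rose from 78.8 CPM ± 0.617 (SD, n = 2 wells) to 101 CPM ± 0.916 (edgeR adjusted p = 0.000516). The other 4 pigs did not pass the threshold for it, and its interaction had an adjusted p of 1.22e-07. Both transcripts had whole-number counts in every well.

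Transcripts called in several pigs did not all move the same way. Pigs P335 and P337 shared 3163 called transcripts, of which 3072 moved in the same direction, where independent lists would give 644.7. Pigs P337 and P342 shared 6007, of which 5346 moved in the same direction (1559 from independent lists), and pigs P335 and P342 shared 2723, with 2305 in the same direction (672.7 from independent lists). Pig P333 went the other way. Of the 1443 transcripts it shared with pig P337, 1335 moved in opposite directions (305.8 from independent lists), as did 1148 of the 1363 shared with pig P342 (319.1) and 696 of the 764 shared with pig P335 (132.4). The wells of different pigs are separate, so the changes compared come from different libraries. The spread they were tested against came from the same fit of all wells, so the lists of calls are not independent. The values from independent lists are therefore only a reference, and the excess over them was not tested. Of the 30784 transcripts tested, 7902 were called in 2 or more pigs, and 2421 of these (30.6%) rose in one pig and fell in another. Among 18895 transcripts with a mean log2 CPM of at least 1, all 6 pigs had the same sign of change for 609 (3.22%), where chance gives 3.12%.

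**Figure D3:**
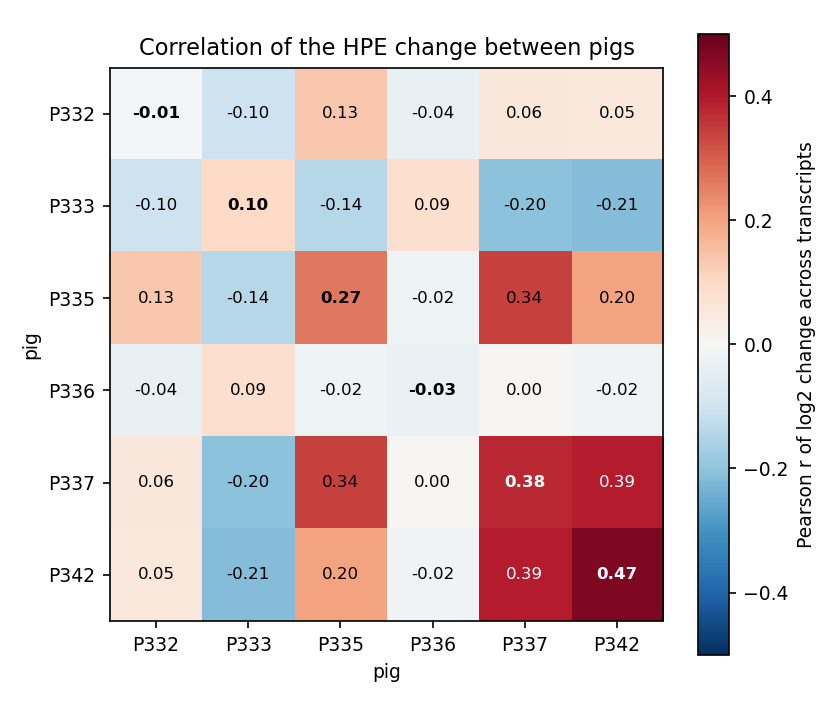
Pearson correlation across transcripts of the log2 change with HPE between each pair of pigs (colour scale and printed value; both axes give the pig), with, on the diagonal in bold, the correlation within a pig between the change from well 1 of each arm and the change from well 2. Values run from -0.215 (pigs P333 and P342) to 0.392 (pigs P337 and P342) off the diagonal. On it they run from -0.0325 (pig P336) to 0.465 (pig P342). All are over the 18895 transcripts with a mean log2 CPM of at least 1. Off the diagonal, the change is that between means over the wells of each arm.

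The same contrast held over the 18895 transcripts with a mean log2 CPM of at least 1, called or not. Across transcripts, which are not independent replicates, the log2 change of pig P337 correlated with that of pig P342 at r = 0.392 (Spearman rho = 0.5) and with that of pig P335 at r = 0.343 (rho = 0.549). The change of pig P333 correlated with those of pigs P335, P337 and P342 at r = -0.143, r = -0.205 and r = -0.215 (rho = -0.34, -0.387 and -0.347). Ranks gave values further from 0 than Pearson's r in other pairs too, in both directions. Pigs P332 and P335 had r = 0.133 and rho = 0.301, and pigs P332 and P333 had r = -0.105 and rho = -0.269. Pig P336 had rho = 0.298 with pig P333 (r = 0.0859) and rho = -0.271, -0.214, -0.175 and -0.124 with pigs P332, P335, P337 and P342 (r = -0.037, -0.0228, 0.004 and -0.0184). By Pearson's r, the changes of pigs P332 and P336 did not repeat between their own wells. It was -0.0105 and -0.0325 between the change from well 1 and that from well 2, and 0.0454 and -0.101 with the wells crossed. In pig P333 it was 0.101 (0.168 crossed), against 0.265 (0.232) in pig P335, 0.375 (0.414) in pig P337 and 0.465 (0.466) in pig P342. Values within a pig rest on single wells and those between pigs on means over wells. Ranks were not taken within a pig, so repetition by rank was not tested. No direction is read from the pairs with pig P332 or pig P336. The mean over the 15 pairs of pigs was r = 0.0348 and rho = 0.0193.

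Differences between animals were also counted within each arm. These tests take all pigs together, unlike the contrasts within a pig, so the counts do not compare the sizes of the differences. Any plate, day or passage that goes with a pig, which the labels used here do not give, cannot be told apart from the animal. In the 13 control wells, 14563 of 28964 transcripts (50.28%) differed between the 6 pigs. In the 13 HPE wells, 15452 of 29123 (53.06%) did.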

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

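The tests on thinned wells, on the 100 most abundant transcripts and on reads shared between transcripts were chosen after the result was seen. So were those on the pig of the HPE wells and on other splits of the wells of pig P342. The predictions on pig P333 name its reversed direction, so they too followed that result. They were set down before their own tests were run. Of 25 groups of 6 pigs searched for a pig far from the others, 4 had one. With independent groups of normal values, chance gives about 1 in 20. The groups here overlap, and some come from transcripts chosen by their p in these data, so the 4 cannot be set against that rate.

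The number of transcripts past the threshold differed between pigs (10940 had a pig-by-treatment interaction), and a different response of the animals and a plate or day shared by the wells of a pig and arm, which the labels used here do not give, stay open and untested. Depth is argued against, since with every well thinned to the same number of reads the lower count of pigs P337 and P342 was still 845 times the higher count of pigs P332 and P336 in edgeR; that size rests on near-zero counts, and DESeq2, at full depth, gave 11324 against 321. Without the 100 most abundant transcripts that ratio was 951, and transcripts with whole-number counts were called 1.42 times as often as the others or more in pigs P337 and P342, so neither abundant transcripts nor shared reads account for the gap. Whether the HPE wells of pigs P337 and P342 came from those pigs cannot be told apart from wells of another of the 6 pigs. Those of pig P337 deviated from their arm's mean most like their own control wells (margin in r at least 0.15). But transcripts on in the control wells of one pig and off in those of another matched pig P337 over pig P336 in only 52.5% (exact 95% interval 44.4 to 60.5). The HPE wells of pig P342 deviated more like pig P336 (lowest margin -0.18). Yet they matched pig P342 over pig P336 in 65.1% (53.8 to 75.2) and over pig P332 in 63.4% (46.9 to 77.9). Undecided matches also occurred in pigs P332, P333 and P335, but not in pig P336. The HPE wells of pig P333 matched their own pig over pig P335 in 53.4% (44 to 62.8) and over pig P337 in 55.9% (47.1 to 64.4). Over pig P342, those of pigs P332 and P335 did so in 65.9% (49.4 to 79.9) and 62.5% (47.4 to 76). The HPE wells of pigs P332, P333 and P335 each deviated most like their own control wells.

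Matching on 34 transcripts that were on or off in the control wells of every pig paired the arms as labelled. The own pig was the best match for the HPE wells of all 6 pigs, and the summed match, 174, was above that of each of the other pairings among 720 (highest other 168; exact one-sided permutation p = 0.00139). The lead over the next pig was 1 transcript in pigs P333 and P337.

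Within pig P342, the real split of the 6 wells called 10017 transcripts and the highest of the other splits called 1; 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05.

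Transcripts called in pig P333 went against those of pigs P335, P337 and P342. A single well as the source is argued against: in all 4 pairings of 1 control with 1 HPE well, the change correlated negatively with the mean change of the other pigs, the highest at r = -0.132. Arm labels exchanged in pig P333 cannot be told apart from a reversed change, and a response of this animal in the other direction was not tested. On an axis from the other pigs' mean control level (0) to their mean HPE level (1), the wells labelled control lay at 0.387 and those labelled HPE at -0.0132, below the midpoint that an exchange was predicted to cross. That midpoint did not part the arms of the other pigs on this axis. There the control wells of pig P336 lay at 0.809 and the HPE wells of pig P332 at 0.289. The control scores of the 5 pigs had an SD of 0.454. The prediction named the midpoint alone, by which 0.387 counts against an exchange. The reading here also asked for a distance of that SD, which the prediction did not name.

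In ENSSSCT00000016326 the change with HPE differed between pigs (interaction adjusted p = 4.65e-07). In ENSSSCT00000010014 it did so too (interaction adjusted p = 1.22e-07), and pig P342 lay far below the other pigs with HPE, at 48.4 CPM. Both transcripts were chosen for a small interaction p, so their flags are no separate evidence. For ENSSSCT00000041298, pig P333 lay far above the other pigs in control wells (23.8 CPM) and in HPE wells (11.6 CPM). The 100 most abundant transcripts held 19.59% of the reads of pig P337 with HPE, far above the other 5 pigs with HPE.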

How the results depend on the processing

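The alternatives that left out single wells, thinned wells to one depth, removed abundant transcripts or kept only whole-number transcripts were chosen after the result was seen. Over 6 pigs the edgeR count was 0 under each alternative on the 12 sums, without each pig or well number in turn (0 to 0), without a replicate block (374 unadjusted p under 0.05) and with pig and well number together as replicate block (0 calls, 5725 unadjusted). It was 1609 with 26 wells and pig as replicate block, 1712 with limma-voom and 91 with DESeq2. The first pair treats wells as replicates, and the cause of the higher counts was not tested. With DESeq2 the counts within pigs were 321 in pig P332, 4141 in pig P333, 6263 in pig P335 and 233 in pig P336. Keeping only the 5915 tested transcripts with whole-number counts gave 7, 963, 1627, 5, 2827 and 3087 calls in pigs P332, P333, P335, P336, P337 and P342, 3524 for the interaction and 4551 between pigs in control wells, where fewer transcripts were tested. In pig P332 there were 5 calls with DESeq2 size factors and 8 without a count filter, and in pig P336 there were 7 with well number as replicate block; the cause was not tested. Well number as a block moved no other count within a pig, for the interaction or between pigs in control wells by over 1.5 times, while over 6 pigs it took the 1609 calls of the 26 wells to 0. Leaving out single wells, with a lone well assumed to vary like the other groups, gave 13 to 25 in pig P332, 214 to 1488 in pig P333, 699 to 4346 in pig P335, 17 to 31 in pig P336, 7377 to 8209 in pig P337 and 8691 to 9389 in pig P342. Leaving out pigs gave 7092 (without pig P342) to 11134 for the interaction and 12250 to 14265 for control wells. The share of variance between pigs was 31.4% in the 500 most variable transcripts and 52.3% on log2(TPM + 1), and that between wells 45.9% and 21.6%, with the cause not tested. Without 1 pig, treatment took 4.75% to 7.1% (7.1% without pig P333) and pig by treatment 17.7% (without pig P333) to 19.1%. The called changes of ENSSSCT00000016326 and ENSSSCT00000010014 in pig P342 kept their sign under each alternative run for them; other called transcripts were followed only as counts. The alternatives for gene sets and named genes with a symbol were not run. With all wells thinned to the shallowest, 1134 transcripts had an unadjusted p under 0.05 over 6 pigs, against 1214. Whether more depth would change the comparison was not tested.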

Other observations

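Of the tests here, those on exchanged arms with edgeR and on the summed change were chosen after the result was seen. The prediction for DESeq2 was set down before its exchanges were run, with its 91 calls already known.

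Exchanging control and HPE within pigs gives 32 distinct groupings of the 12 sums. The real arms gave 1214 transcripts with an unadjusted p under 0.05 in edgeR, and 7 of the 32 groupings, the real one included, gave as many. The highest of the others gave 6075, with pigs P333 and P336 exchanged, several times the real count, and exchanging pig P333 alone gave 4134. Chance could not be excluded for the direction shared by all 6 pigs. The number of calls was 0 in each of the 32. A second set of 99 groupings of the 12 sums, the real one included and drawn from 462, could also put both sums of a pig in 1 arm. Of these, 20 gave as many unadjusted p under 0.05, again counting the real one. Most parted only 2 or 4 of the 6 pairs (45 and 46 groupings), and the highest counts, 8247 and 2589 calls, came with 2 pairs parted. Among the 8 that parted all 6 pairs, 2 gave as many, the highest 3433. These 8 are among the 32 groupings above. Groupings that differ only in pairs not parted give the same fit, so the 99 hold repeats. Groupings with several times the real count point to a structure of the samples. With pig as a block, each grouping measures only differences between the arms within the pairs it parts, so no structure apart from the arms was tested. Where all 6 pairs were parted, the higher counts came from reversing the change in some pigs.

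The 91 transcripts called by DESeq2 over 6 pigs were tested in the same way. As many calls came from 7 of the 32 groupings, and the highest of the others gave 3667, again with pigs P333 and P336 exchanged, so chance could not be excluded for this count either.

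A further hypothesis was that the changes of the 6 pigs add up in a common direction even where single transcripts miss the threshold. The mean square of the log2 change summed over pigs was 5.639 with the real arms and 7.837 at the highest of the other sign patterns, and 5 of 32 patterns gave a value as large (exact permutation p = 0.156, one-sided). The data gave no evidence for a common direction by this test.

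Each pig was also placed on an axis built from the other 5 pigs alone, from their mean control level (0) to their mean HPE level (1); the axis differs from pig to pig, so positions are not comparable between pigs. Pig P336 lay at 1.14 in control and 1.14 in HPE wells, and pig P332 at -0.0244 and 0.0598. These are the pigs with 12 and 3 transcripts past the threshold. The control wells of pig P336 lay near the mean HPE level of the other pigs, whose highest control score on that axis was 0.181. On their own axes, pig P335 went from 0.0828 to 0.632, pig P337 from 0.0534 to 1.09 and pig P342 from 0.19 to 0.84. No explanation was tested for these positions.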
